A study of Rattus norvegicus with 29 samples.

How the data were processed

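RNA from the duodenum of 29 male wild-type Long-Evans rats, aged 8 to 10 weeks, was measured on Affymetrix gene arrays with 1 array per animal. The labels put the animals in 5 groups: RYGB surgery (6 arrays), its sham operation (5 arrays), VSG surgery (6 arrays), its sham operation (6 arrays), and the VSG sham operation with paired feeding (6 arrays). RYGB is Roux-en-Y gastric bypass and VSG is vertical sleeve gastrectomy, in which, per the labels, about 80% of the stomach was transected. The labels call the samples of a group biological replicates. How long after surgery the tissue was taken is not given in the sources used here.

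The values are deposited log2 expression values, 1 per probe set and array, made with RMA in Affymetrix Expression Console version 1.3.0.187, per the submitters' processing notes. RMA as commonly run corrects the background, quantile-normalizes the arrays and summarises the probes. The chip definition, the genome build and any filter are not given in the sources used here, so no coordinates are reported. The arrays were already comparable in level: their medians over all rows lay between 2.80 and 2.97. No array was a copy of another, since the highest correlation between any pair over the 36685 rows was 0.977. Arrays give no read depth, so the number of arrays limits the precision.

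Rows were named through the platform's gene annotation. Of the 36685 rows, 14824 had 1 gene symbol, 829 had several and 21032 were not named here. Symbols were updated through their Entrez numbers with the gene table of the GRCr8 assembly, in which 154 numbers were not found and kept their old symbol. A gene was represented by its row with the highest mean over the 29 arrays, which mattered for 234 genes, and 14557 genes were tested without an intensity filter.

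One linear model with 5 group means was fitted to all 29 arrays with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes). The contrasts were RYGB against its sham, VSG against its sham, VSG against pair-fed sham, pair-fed sham against sham, the RYGB effect minus the VSG effect, and the VSG sham against the RYGB sham. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a contrast. A gene was called at an adjusted p under 0.05, and values are log2 fold changes ± standard error (SE).

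Before the data were examined, 35 gene lists were fixed: iron absorption and iron handling, hypoxia response, gut hormones, enteroendocrine granule and transcription factors, sugar and peptide digestion and absorption, lipid absorption and chylomicrons, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and ketogenesis, bile acid response and transport, xenobiotic metabolism, calcium and vitamin D response, zinc and copper handling, cell cycle, intestinal stem cells and Wnt targets, goblet cells, Paneth cells and antimicrobial response, Brunner gland with gastric and pyloric epithelium, exocrine pancreas, tuft cells and type 2 response, mast cells, T cells and natural killer cells, B cells and plasma cells, macrophages and myeloid cells, interferon response, MHC class II, smooth muscle, enteric neurons and glia, fibroblasts and extracellular matrix, endothelium, red blood cells, adipose tissue, immediate early and heat shock response, unfolded protein and amino acid stress response, and circadian clock. Of their 725 members, 536 were measured in named rows. A list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 140 tests of 35 lists in 4 comparisons. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Members were also counted with p-values adjusted over the list alone.

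The rule for the genes named in the text was also fixed beforehand. For each of the 4 comparisons of surgery or feeding it took the 8 largest and 8 smallest fold changes among called genes, every called member of the iron and gut hormone lists, up to 4 members with the smallest p from each other called list, and in every comparison Slc11a2, Cybrd1, Slc40a1, Heph, Tfrc, Fth1, Hmox1, Gcg, Gip, Cck, Sct and Ghrl. Where nothing was called it took the 5 genes with the smallest p. For the difference of the surgeries' effects and for the shams it took 5 genes in each direction. Symbols of unnamed loci and of olfactory, vomeronasal or immunoglobulin segment genes were passed over. Slc11a2, Fth1, Cck and Sct had no row of their own and were not analysed here. A gene named outside this rule is said to have been chosen after its values were seen.

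The effects of the surgeries were compared by their Pearson correlation across genes, tested by permuting the group labels within each surgery and its sham 100 times. Alternatives fixed beforehand were leaving out the lowest 33.3% of genes by mean, testing all rows, averaging the rows of a gene, a trended and robust prior, centring arrays on their median, a further quantile normalization, array weights, fitting only the compared groups, a replicate block, each array left out in turn, and a fold threshold of 1.5. A pair of alternatives was chosen after the data were seen: the mean of the exocrine pancreas list of each array as a covariate, and leaving out arrays with such a mean above 8. The arrays kept by this cut still differed in that mean between surgery and sham groups.

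The pipeline was tested on simulated data of the same size, with each gene drawn independently from its fitted mean and residual spread and 50 genes changed per fold size among 14557. In the simulated RYGB comparison 60.0% of genes changed 1.5-fold and 92.0% of those changed 2-fold were recovered, with 9 unchanged genes called. The simulated VSG against sham comparison recovered 50.0% and 96.0% with 7 unchanged genes called, VSG against pair-fed sham 68.0% and 90.0% with 14, and pair-fed sham against sham 60.0% and 86.0% with 9. Of 1000 simulated lists without a shift, camera gave an unadjusted p under 0.05 to 2.6% in the RYGB comparison, 3.4% in VSG against sham, 2.6% in VSG against pair-fed sham and 2.9% in pair-fed sham against sham. The simulated genes were independent, so these shares cannot show how often camera calls real lists of correlated genes. Pairs of measured exocrine pancreas genes, for example, had a median r of 0.963 within groups.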

Results

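Gene expression was measured in the duodenum of 29 rats after bariatric or sham surgery. The series title asks about the intestinal iron absorption machinery, gut hormone secretion and systemic metabolism. RYGB, which leads food past the duodenum, was compared with its sham operation (6 and 5 rats). VSG, which narrows the stomach and leaves food passing through the duodenum, was compared with its sham operation and with sham rats given paired feeding (6 rats each). All values below are log2 RMA values from 1 array per rat.

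Transcripts of the exocrine pancreas, which adjoins the duodenum, differed strongly between arrays of a single group. The mean of the 16 measured acinar genes, among them Prss1, Ctrb1 and Cela3b, ranged from 3.08 to 9.18 in RYGB, from 2.88 to 5.93 in its sham, from 4.96 to 8.65 in VSG, from 2.93 to 8.48 in the VSG sham and from 2.75 to 9.48 in pair-fed sham. Group means were 7.17 ± 2.35 (SD, n = 6) after RYGB and 3.66 ± 1.28 (SD, n = 5) in its sham, a difference of 3.51 (exact permutation p = 0.0216, two-sided, adjusted p = 0.0866 over 4 comparisons). They were 7.27 ± 1.28 after VSG, 5.24 ± 2.17 in its sham (exact p = 0.0887, adjusted p = 0.177) and 5.80 ± 2.92 in pair-fed sham (exact p = 0.271, adjusted p = 0.361). Pair-fed sham and sham differed by 0.56 (exact p = 0.684), and by -0.13 and -0.18 without pair-fed replicate 1 or 6, with a range from -0.18 to 1.21 over single arrays left out. Left out in the same way, the RYGB difference ran from 3.11 to 4.33 (exact p from 0.0159 to 0.0571). That of VSG and its sham passed an unadjusted 0.05 without VSG replicate 4 (2.49, exact p = 0.0433) or sham replicate 1 (2.68, exact p = 0.0216). That of VSG and pair-fed sham was 0.95, 0.86 and 2.21 without pair-fed replicate 3, 5 or 6 (exact p = 0.476, 0.504 and 0.0996). Limma called none of the 16 genes in these 4 comparisons. Prss1, for example, differed by 5.33 ± 1.62 between RYGB and sham (adjusted p = 0.0769). The size of this difference is inexact, since Prss1 was low in the RYGB sham arrays other than replicate 1 (7.92). It was at 0.96 to 1.96 there, under array medians of 2.85 to 2.91. The first principal component of all genes, with 13.8% of the variance, followed this mean (r = -0.919).

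**Figure D1:**
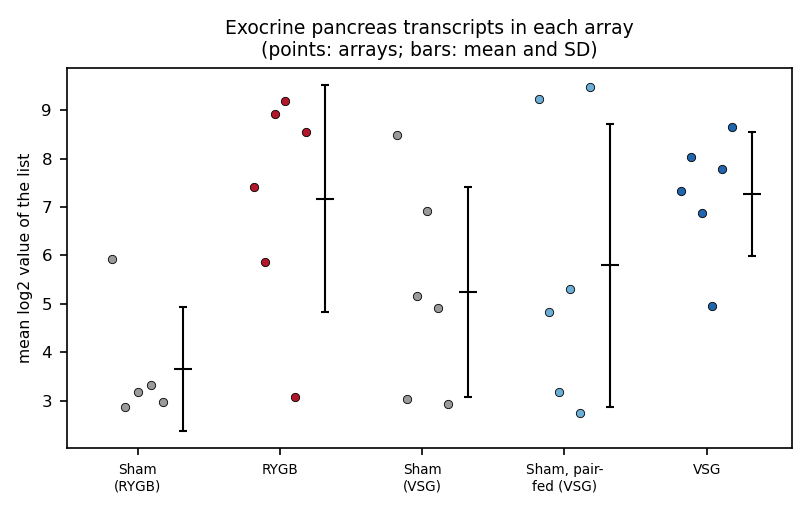
Mean log2 value of the 16 measured exocrine pancreas genes (vertical axis) in each array, by group, with the group mean and SD beside the points. Arrays of one group span up to 9.48 in the pair-fed shams, while 4 of the 5 RYGB sham arrays lie at or below 3.33.

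RYGB was first compared with its sham. The RYGB series has no pair-fed sham, so the bypass cannot be told apart from any change in food intake. Of the 25 measured members of the iron list 6 rose, 1 fell and 18 did not pass after RYGB (camera adjusted p = 0.0299, and adjusted p = 0.335 with an estimated correlation). Tfrc, the transferrin receptor, was 2.22-fold higher (log2 fold change 1.15 ± 0.12, adjusted p = 2.85e-07), Cybrd1, the ferric reductase of the brush border, 2.25-fold higher (1.17 ± 0.29, adjusted p = 0.0225) and Slc40a1, the iron exporter ferroportin, 1.61-fold higher (0.69 ± 0.16, adjusted p = 0.00956). For each of these 3 genes all 6 RYGB arrays lay above all 5 sham arrays. Cybrd1 was not called without RYGB sham replicate 2, 4 or 5 (1.10, 1.12 and 0.96, adjusted p = 0.0689, 0.0587 and 0.0918). The iron list was not called without RYGB replicate 3 or 6 or sham replicate 3 or 5 (0.17, 0.17, 0.18 and 0.15, adjusted p = 0.0672, 0.0538, 0.0554 and 0.0847). Plin2, a coat protein of lipid droplets, fell 2.91-fold (-1.54 ± 0.12, adjusted p = 1.36e-09) and Angptl4, an inhibitor of lipoprotein lipase, 6.20-fold (-2.63 ± 0.21, adjusted p = 1.36e-09). In all, limma called 385 of 14557 genes, 184 higher and 201 lower, of which 218 changed at least 1.5-fold.

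In the iron list 6 members rose and 1 fell also when adjusted over the list alone. Beside the 3 genes above, Abcg2, an exporter of porphyrins and other compounds, rose 2.42-fold (1.28 ± 0.17), Ireb2, the iron-regulatory protein 2, 1.48-fold (0.56 ± 0.15) and Epas1, the hypoxia-inducible factor 2 alpha, 1.29-fold (0.37 ± 0.09). Slc25a28, a mitochondrial iron carrier, fell 1.84-fold (-0.88 ± 0.11). Ireb2 was not called without RYGB replicate 1, 2, 3 or 6 or sham replicate 2, 3 or 5 (0.50 to 0.58, adjusted p from 0.0578 to 0.113). Epas1 was not called without RYGB replicate 1 or 3 or sham replicate 2 or 4 (0.34 to 0.36, adjusted p from 0.0509 to 0.0552). Heph, at 0.19 ± 0.13, and Hmox1, at 0.03 ± 0.26, did not pass (adjusted p = 0.574 and 0.98). The list as a whole had a mean of 0.19 and a median of 0.03, with 15 members above 0 and 10 below. With the pancreas mean of each array as a covariate the mean was 0.18 (adjusted p = 0.0737).

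The hypoxia list had the largest upward shift among the lists other than exocrine pancreas, a mean of 0.67 over 16 measured members, and it was the only list of this comparison to keep its call with an estimated correlation (adjusted p = 4.28e-15 and 0.00442). Of its members 9 rose, none fell and 7 did not pass, and 10 rose when adjusted over the list alone. Ankrd37 rose 5.53-fold (2.47 ± 0.37), Egln3, the oxygen-sensing prolyl hydroxylase 3, 2.89-fold (1.53 ± 0.16), Adm, the peptide adrenomedullin, 2.58-fold (1.37 ± 0.24) and Pgk1, a glycolytic enzyme, 1.64-fold (0.71 ± 0.12). Zinc and copper handling shifted up by 0.21, with a median of 0.15 and 10 of 12 members above 0. Its 1 called member was the manganese and zinc transporter Slc30a10, 2.97-fold higher (1.57 ± 0.19). The list's adjusted p was 0.0439, with adjusted p = 0.195 with an estimated correlation and adjusted p = 0.0573 with the pancreas covariate. It was not called without RYGB replicate 3 or 5 or sham replicate 2 or 5 (0.20, 0.18, 0.20 and 0.19, adjusted p = 0.0672, 0.105, 0.076 and 0.0811).

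**Figure D2:**
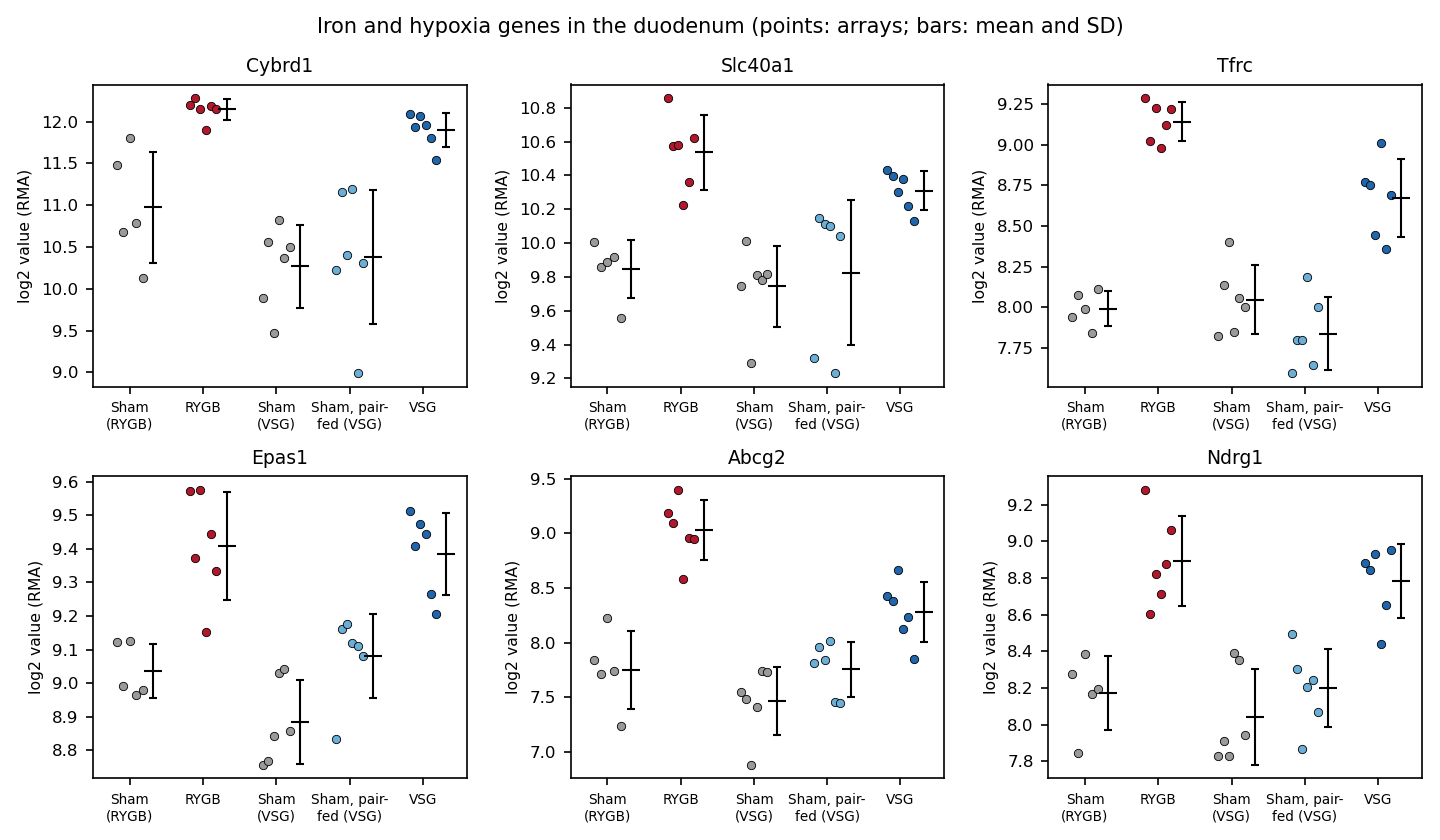
Log2 values (vertical axes) of Cybrd1, Slc40a1, Tfrc, Epas1, Abcg2 and Ndrg1 in each array, by group, with the group mean and SD. For Cybrd1, Slc40a1 and Tfrc the 6 RYGB arrays lie above the 5 sham arrays, and Cybrd1 lies above both sham groups in the 6 VSG arrays.

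The lists of cholesterol synthesis, fatty acid oxidation, lipid absorption and fatty acid synthesis shifted down after RYGB by camera, and none kept its call with an estimated correlation. Of 15 measured genes of cholesterol synthesis 7 fell and 8 did not pass (8 fell when adjusted over the list alone), including Insig1, the sterol-sensing regulator of the pathway, 2.30-fold lower (-1.20 ± 0.17), and the enzymes Fdft1 (-0.76 ± 0.17), Mvd (-0.74 ± 0.17) and Nsdhl (-0.58 ± 0.14). The list shifted by -0.50 (adjusted p = 3.40e-10, and adjusted p = 0.195 with an estimated correlation). Of 28 genes of fatty acid oxidation and ketogenesis 5 fell and 23 did not pass, 15 falling when adjusted over the list alone. They included Pdk4 (-1.15 ± 0.24), Cpt1a (-0.55 ± 0.12) and Cpt2 (-0.52 ± 0.12), the carnitine palmitoyltransferases, beside Angptl4. That list shifted by -0.45 (adjusted p = 2.50e-11, and adjusted p = 0.0677 with an estimated correlation). Fdft1 and Nsdhl were not called without RYGB sham replicate 4 (-0.66 and -0.50, adjusted p = 0.0527 and 0.0693), nor Cpt2 without sham replicate 1 (-0.45, adjusted p = 0.054).

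Lipid absorption and chylomicrons had 3 of 17 members lower, Plin2, Dgat2, the triglyceride-forming acyltransferase (2.99-fold, -1.58 ± 0.17), and Apoc2, the cofactor of lipoprotein lipase (4.04-fold, -2.01 ± 0.20). Adjusted over the list alone 2 members rose and 4 fell, and Apoa4 was at -0.25 ± 0.08 (adjusted p = 0.0655). The shift was -0.31 (adjusted p = 0.00286, and adjusted p = 0.335 with an estimated correlation), and -0.25 without the arrays high in pancreas transcripts (adjusted p = 0.0519). In fatty acid synthesis Srebf1, the lipogenic transcription factor (-0.81 ± 0.18), Me1 (-0.52 ± 0.12) and Pklr (-0.45 ± 0.11) fell while Scd, the stearoyl-CoA desaturase, rose (1.05 ± 0.26). Of its 14 members 10 did not pass, and adjusted over the list alone 1 rose and 6 fell. The shift was -0.18 (adjusted p = 0.00343, and adjusted p = 0.335 with an estimated correlation), and -0.11 without RYGB replicate 1 (adjusted p = 0.0388). Pklr was not called without RYGB sham replicate 1 (-0.41, adjusted p = 0.0509). Scd was not called without RYGB replicate 2 or 6 or sham replicate 4 or 5 (0.91 to 1.00, adjusted p from 0.0513 to 0.0781). The 18 lower genes of these 4 lists had a median of -0.75, which was -0.63 with the pancreas mean as a covariate, and 7 of them stayed called.

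**Figure D3:**
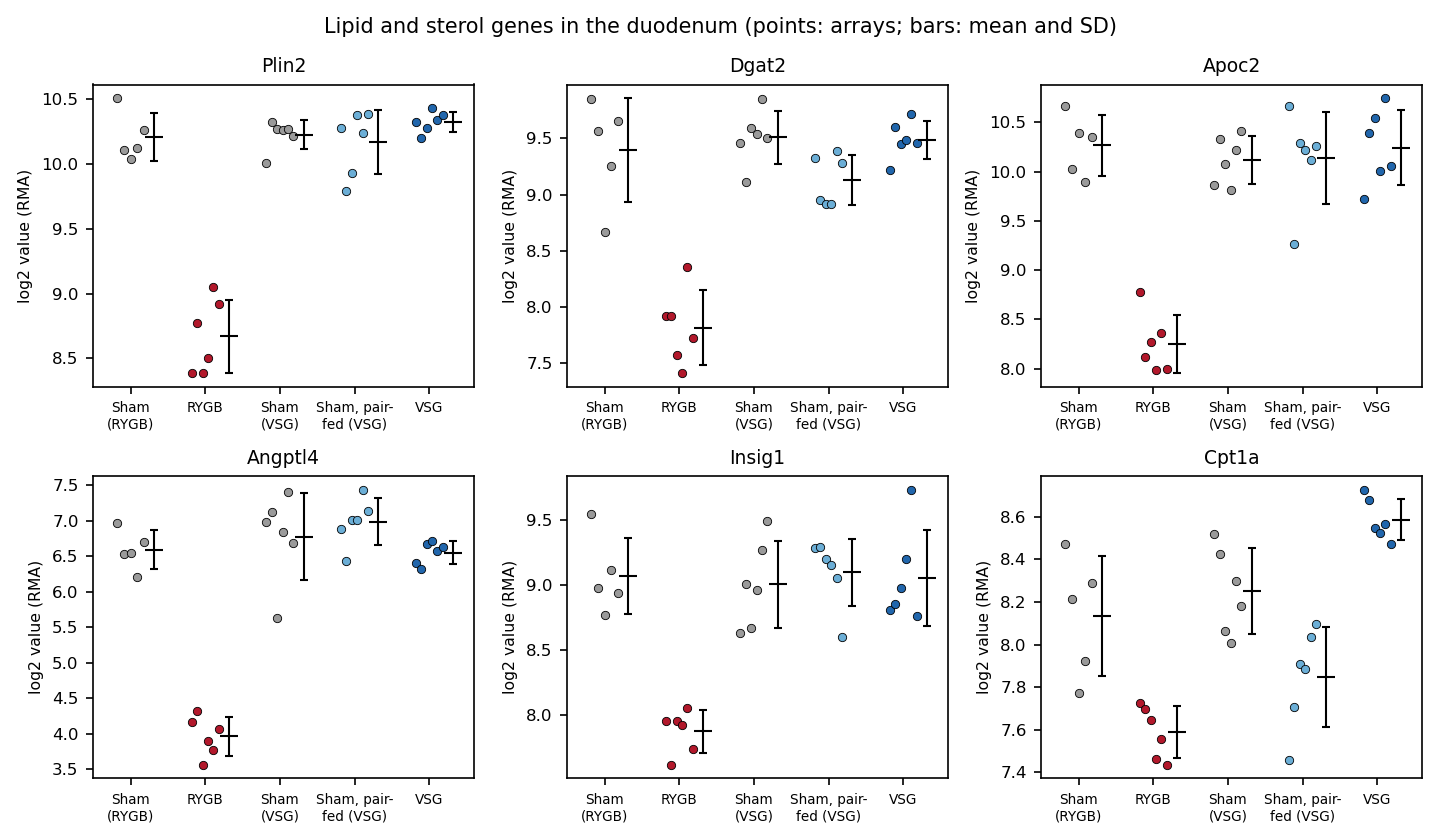
Log2 values (vertical axes) of Plin2, Dgat2, Apoc2, Angptl4, Insig1 and Cpt1a in each array, by group, with the group mean and SD. The RYGB arrays are lower than their shams, by 1.54 for Plin2 and 2.63 for Angptl4 on average.

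In xenobiotic metabolism 7 of 27 members fell and 20 did not pass (2 rose and 8 fell when adjusted over the list alone), among them Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor, 5.52-fold lower (-2.46 ± 0.55), Aldh1a1 (-0.76 ± 0.16), Gclm (-0.56 ± 0.13) and Cyp2j4 (-0.45 ± 0.10). The list shifted by -0.31 (adjusted p = 0.000217, and adjusted p = 0.195 with an estimated correlation). The cell cycle list shifted by -0.26 (adjusted p = 6.51e-08, and adjusted p = 0.195 with an estimated correlation), with 27 of 28 members below 0. Of these only Prc1 (-0.74 ± 0.14) and Tyms (-0.58 ± 0.13) passed alone, 12 fell when adjusted over the list alone, and Pcna, the replication clamp, rose 2.33-fold (1.22 ± 0.13). In the immediate early and heat shock list, Fos (-0.99 ± 0.19) and Jun (-0.69 ± 0.16) fell, also when adjusted over the list alone, and 14 of 16 members did not pass, with Hspb1 at -0.61 ± 0.26 and Zfp36 at -0.61 ± 0.23. Its shift was -0.26 (adjusted p = 0.0252, and adjusted p = 0.524 with an estimated correlation), and -0.20 without the arrays high in pancreas transcripts (adjusted p = 0.128). It was not called without RYGB replicate 2 or 4 or sham replicate 1 (-0.24, -0.22 and -0.20, adjusted p = 0.0548, 0.0696 and 0.125). Jun was not called without RYGB sham replicate 1 (-0.61, adjusted p = 0.0575).

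Lists of stromal and immune cells shifted as well. Fibroblasts and extracellular matrix shifted by -0.37 (adjusted p = 2.48e-07, and adjusted p = 0.168 with an estimated correlation), with Timp1 (-0.91 ± 0.23), Lum (-0.59 ± 0.15) and Col6a1 (-0.52 ± 0.14) lower, Col3a1 at -0.53 ± 0.15 (adjusted p = 0.0597) and 10 of 17 members lower when adjusted over the list alone. Enteric neurons and glia shifted by -0.26 (adjusted p = 0.0398, and adjusted p = 0.414 with an estimated correlation) with Vip, vasoactive intestinal peptide, lower (-1.22 ± 0.24) and the other 12 members, such as Gal, Grp and Syt1, not called. Macrophages and myeloid cells shifted by -0.24 (adjusted p = 0.00462, and adjusted p = 0.595 with an estimated correlation) with the chemokine Ccl2 lower (-0.81 ± 0.19), Ccr2 at -0.65 ± 0.21 and 2 of 20 lower when adjusted over the list alone. Smooth muscle, with Actg2 at -0.34 ± 0.17 and none of 11 members called, shifted by -0.22 (adjusted p = 0.0314, and adjusted p = 0.679 with an estimated correlation). MHC class II shifted up by 0.32 (adjusted p = 0.00161, and adjusted p = 0.444 with an estimated correlation), with none of 7 members called, 2 higher when adjusted over the list alone, and RT1-DMb at 0.61 ± 0.18. Paneth cells and antimicrobial response shifted up by 0.18 (adjusted p = 0.00685, and adjusted p = 0.195 with an estimated correlation). There Duoxa2, the maturation factor of an epithelial oxidase, rose 3.09-fold (1.63 ± 0.24) and the other 18 members did not pass, with Duox2 at 0.77 ± 0.28 and Reg3g at -1.64 ± 0.48. Adjusted over the list alone 4 rose and 2 fell. The exocrine pancreas list shifted up by 3.51 (adjusted p = 2.08e-11, and adjusted p = 0.335 with an estimated correlation). Its 16 members were called when adjusted over the list alone. With the pancreas mean as a covariate, enteric neurons and glia were at -0.19 (adjusted p = 0.131), smooth muscle at -0.12 (adjusted p = 0.383), MHC class II at 0.22 (adjusted p = 0.0737) and Paneth cells and antimicrobial response at 0.11 (adjusted p = 0.0795), none of them called. Without the arrays high in pancreas transcripts enteric neurons and glia (-0.26, adjusted p = 0.0865), smooth muscle (-0.18, adjusted p = 0.139) and MHC class II (0.22, adjusted p = 0.0898) were not called either. The mean of enteric neurons and glia was 3.98 in RYGB sham replicate 4 and 3.61 to 3.68 in the other sham arrays, and the list was at -0.20 without it (adjusted p = 0.153). It was not called without RYGB replicate 1, 2 or 3 either (-0.22, -0.25 and -0.26, adjusted p = 0.0909, 0.0652 and 0.0608). Smooth muscle was not called without RYGB replicate 1, 2 or 3 or sham replicate 4 or 5 (-0.15, -0.20, -0.17, -0.20 and -0.20, adjusted p = 0.168, 0.0626, 0.101, 0.0528 and 0.0783). Among the genes, Timp1 was not called without RYGB replicate 1 or 6 or sham replicate 3 or 4 (adjusted p from 0.0524 to 0.0968), and Ccl2 without sham replicate 1 or 2 (adjusted p = 0.0509 and 0.0709). Neither was Lum without RYGB replicate 1, 3 or 6 or sham replicates 1 to 4 (adjusted p from 0.0501 to 0.104). Col6a1 was not called without RYGB replicate 1, 3 or 6 or sham replicate 1, 2, 4 or 5 (adjusted p from 0.0544 to 0.128).

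Among the called genes the 6 largest rises were those of Ankrd37 above and of Clca5 (2.42 ± 0.24), Nedd9 (1.97 ± 0.14), Tbc1d21 (1.98 ± 0.21), Cbln3 (1.91 ± 0.27) and Csta, a cysteine protease inhibitor 12.4-fold higher (3.63 ± 0.39). Csta may lie near background outside RYGB, which would make its fold inexact. In the VSG arrays other than replicate 4 (2.91) it was at 1.24 to 1.80, under array medians of 2.83 to 2.92. Cyp24a1, the vitamin D hydroxylase of the calcium and vitamin D list, was 2.99-fold higher (1.58 ± 0.35). The 8 largest falls among them were those of Angptl4, Cyp1a1 and Apoc2 above and of Rab30, a small GTPase, 10.2-fold lower (-3.35 ± 0.37), the phosphatase Phospho1, 7.60-fold lower (-2.93 ± 0.23), Ly6m (-2.73 ± 0.39), Pck1, the gluconeogenic carboxykinase (-2.06 ± 0.39), and Spink4 of the goblet cell list (-2.01 ± 0.25). Of 14 measured gut hormone genes, 1 rose and 1 fell when adjusted over the list alone. Adjusted over all genes, only Guca2a of these was called, which encodes guanylin and rose 1.34-fold (0.42 ± 0.11, adjusted p = 0.0405). It was not called with the RYGB groups alone (adjusted p = 0.0798), with the pancreas covariate (0.32, adjusted p = 0.287) or without the arrays high in pancreas transcripts (0.40, adjusted p = 0.14). Leaving out any 1 array other than RYGB sham replicate 3 also ended its call (0.36 to 0.44, adjusted p from 0.0527 to 0.124). Gcg, the precursor of the glucagon-like peptides, was at -0.23 ± 0.29, Gip at 0.21 ± 0.13 and Ghrl at 0.15 ± 0.14, none of them called. Fitting the RYGB groups alone called 192 genes in place of 385, the pancreas covariate 218, and leaving out the arrays high in pancreas transcripts (3 RYGB arrays and none of its sham) 170. The fit of the RYGB groups alone ended 13 of 54 named calls, at unchanged log2 values. These were Ccl2, Col6a1, Cpt1a, Cyp1a1, Cyp24a1, Epas1, Guca2a, Ireb2, Jun, Lum, Pklr, Scd and Tyms (adjusted p from 0.0515 to 0.198). Of 54 named called genes 36 kept their call with the covariate. Those that did not were Cybrd1, at 1.14 ± 0.34 (adjusted p = 0.0978), Guca2a, Ireb2, Aldh1a1, Cyp1a1, Cyp2j4, Ccl2, Col6a1, Lum, Timp1, Cpt1a, Cpt2, Fdft1, Mvd, Nsdhl, Me1, Pklr and Scd, at adjusted p-values from 0.0503 to 0.287. Without the arrays high in pancreas transcripts 26 of the 54 were not called (adjusted p from 0.0559 to 0.254), these genes except Ccl2, and Slc40a1, Cyp24a1, Fos, Jun, Gclm, Pck1, Pdk4, Srebf1 and Vip. The log2 values of the lost calls were 73.8% to 114% of those above with the covariate (median 88.6%) and 65.4% to 119% without these arrays (median 96.5%), where Pck1 (-1.34) and Pdk4 (-0.76) moved by over 1.5-fold.

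The other 18 lists did not pass in RYGB against sham. Sugar and peptide digestion and absorption had a mean of -0.018 and a median of 0.010 over 18 members (adjusted p = 0.601), with 2 called members higher, 2 lower and 14 not passing. Gut hormones had a mean of -0.06 (adjusted p = 0.971) and enteroendocrine granule and transcription factors -0.07 (adjusted p = 0.584). Bile acid response and transport had a mean of 0.029 (adjusted p = 0.985), and intestinal stem cells and Wnt targets 0.026 (adjusted p = 0.813). Calcium and vitamin D response had a mean of 0.011 (adjusted p = 0.844), with 2 members higher, Cyp24a1 among them, and 1 lower. Goblet cells had a mean of 0.025 (adjusted p = 0.839), with Spink4 lower and 14 of 15 members not called, and the Brunner gland with gastric and pyloric epithelium had a mean of 0.12 (adjusted p = 0.869). Tuft cells had a mean of -0.017 (adjusted p = 0.933), mast cells -0.06 (adjusted p = 0.968), T cells and natural killer cells 0.14 (adjusted p = 0.203) and the interferon response -0.20 (adjusted p = 0.139). B cells and plasma cells had a mean of 0.06 and a median of -0.015 (adjusted p = 0.601), and adipose tissue a mean of -0.09 and a median of 0.07 (adjusted p = 0.699). Endothelium had a mean of -0.09 (adjusted p = 0.447), red blood cells 0.015 (adjusted p = 0.969), the unfolded protein and amino acid stress response 0.05 (adjusted p = 0.174) and the circadian clock 0.05 (adjusted p = 0.836).

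VSG was compared with its sham to show the effect of a surgery that leaves the duodenum in the path of food. Among called genes the largest rise was in Cybrd1, 3.10-fold higher (log2 fold change 1.63 ± 0.28, adjusted p = 0.00911), with all 6 VSG arrays above all 6 sham arrays. Tfrc was 1.54-fold higher (0.63 ± 0.11, adjusted p = 0.0129), Epas1 1.42-fold (0.50 ± 0.09, adjusted p = 0.00911) and Abcg2 1.76-fold (0.82 ± 0.16, adjusted p = 0.0297). Slc40a1 was at 0.57 ± 0.15 and did not pass (adjusted p = 0.137). Slc30a10 rose 2.02-fold (1.01 ± 0.19), and Klk10, a secreted serine protease, fell 2.35-fold (-1.23 ± 0.23). Limma called 26 of 14557 genes, 22 higher and 4 lower, the lower ones being Klk10, Cyp4f5 (-1.13 ± 0.18), Smim1 (-0.76 ± 0.16) and Capn13 (-0.66 ± 0.14). Slc30a10 and Klk10 were not called without VSG replicate 1, 2 or 3 (0.94 to 0.95, adjusted p from 0.0519 to 0.0613, and -1.15 to -1.10, adjusted p from 0.0545 to 0.0773). Abcg2 was not called without VSG replicate 1, 2 or 3 or sham replicate 2, 3 or 4 (0.70 to 0.82, adjusted p from 0.0506 to 0.106). Leaving out any 1 of the 12 arrays other than VSG replicate 1 or 5 ended the call of Smim1 (adjusted p from 0.053 to 0.144), and any other than sham replicate 6 that of Capn13 (adjusted p from 0.0508 to 0.122).

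The iron list shifted up by 0.18 after VSG (adjusted p = 0.00133, and adjusted p = 0.155 with an estimated correlation), with 4 of 25 members higher and 21 not called, and 5 higher and 1 lower when adjusted over the list alone. The hypoxia list shifted up by 0.28 (adjusted p = 2.98e-06, and adjusted p = 0.123 with an estimated correlation). In it Ndrg1 rose 1.67-fold (0.74 ± 0.13), 15 of 16 members did not pass, 3 rose when adjusted over the list alone, and Car9, Pgk1 and Egln3 were at 0.63 ± 0.18, 0.44 ± 0.12 and 0.38 ± 0.15. Calcium and vitamin D response shifted up by 0.27 (adjusted p = 0.00177, and adjusted p = 0.134 with an estimated correlation), with Cldn2, a claudin of leaky tight junctions, 1.65-fold higher (0.72 ± 0.15), Trpv6, the apical calcium channel, at 1.00 ± 0.33 and not called, and 3 of 10 members higher when adjusted over the list alone. Zinc and copper handling shifted up by 0.19 with Slc30a10 as its only called member of 12 (adjusted p = 0.00133, and adjusted p = 0.0677 with an estimated correlation). Cldn2 was not called without VSG replicate 1, 2, 3 or 6 or sham replicate 3, 4 or 6 (0.61 to 0.74, adjusted p from 0.0618 to 0.106).

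Further lists shifted after VSG with at most 1 called member each. The unfolded protein and amino acid stress list shifted up by 0.13 (adjusted p = 0.0181, and adjusted p = 0.443 with an estimated correlation), with the chaperone Dnajb9 higher (0.58 ± 0.12) and 15 of 16 members not called. Immediate early and heat shock genes shifted up by 0.24 (adjusted p = 0.0103, and adjusted p = 0.444 with an estimated correlation), where none of 16 passed, 1 rose when adjusted over the list alone, and Dusp1 was at 0.72 ± 0.20. MHC class II shifted up by 0.24 (adjusted p = 0.00289, and adjusted p = 0.483 with an estimated correlation) and mast cells by 0.18 (adjusted p = 0.0439, and adjusted p = 0.404 with an estimated correlation), with RT1-DMa at 0.41 ± 0.13 and Cpa3 at 0.44 ± 0.25, neither called. The cell cycle list shifted by -0.19 (adjusted p = 2.98e-06, and adjusted p = 0.255 with an estimated correlation), with 23 of 28 members below 0, none called, and Cenpf at -0.49 ± 0.17. Smooth muscle shifted by -0.15 (adjusted p = 0.0398, and adjusted p = 0.679 with an estimated correlation), with Myl9 at -0.25 ± 0.11 and none of 11 members called. Exocrine pancreas shifted up by 2.03 (adjusted p = 4.86e-07, and adjusted p = 0.484 with an estimated correlation), none of its members being called. With the pancreas mean as a covariate the stress list (0.11, adjusted p = 0.068), immediate early genes (0.20, adjusted p = 0.0638), MHC class II (0.17, adjusted p = 0.0573), mast cells (0.20, adjusted p = 0.0534) and smooth muscle (-0.09, adjusted p = 0.276) were not called. Without the arrays high in pancreas transcripts mast cells (0.19, adjusted p = 0.0668) and the stress list (0.11, adjusted p = 0.0973) were not called. The mean of mast cells was 4.26 in VSG replicate 5 and 3.80 to 3.90 in the other VSG arrays, and the list was at 0.11 without it (adjusted p = 0.27). It was not called without sham replicate 1, 3, 4 or 6 either (0.16, 0.16, 0.16 and 0.17, adjusted p = 0.092, 0.074, 0.0755 and 0.0697). Immediate early genes were not called without VSG replicate 3 or 6 or sham replicate 3 (0.14, 0.19 and 0.18, adjusted p = 0.145, 0.0786 and 0.0841). Smooth muscle was not called without VSG replicate 1, 3 or 4 or sham replicate 2 or 4 (-0.13, -0.10, -0.15, -0.14 and -0.06, adjusted p = 0.12, 0.217, 0.0521, 0.0647 and 0.569). Cxcl16 and Plscr1 (both 0.80 ± 0.17) and Stc1 (0.92 ± 0.20) also rose. These 3 genes and Dnajb9 lost their calls without 9, 8, 11 and 6 of the 12 arrays, VSG replicates 1 and 3 among them for each (adjusted p of at most 0.122, 0.124, 0.15 and 0.106). Among gut hormones Gcg was at -0.58 ± 0.28, Ghrl at -0.22 ± 0.13 and Gip at 0.08 ± 0.13, Heph was at 0.19 ± 0.13 and Hmox1 at -0.02 ± 0.25, and none of these passed.

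With the pancreas covariate 5 of 15 named called genes, Cybrd1, Tfrc, Epas1, Ndrg1 and Cyp4f5, kept their call. Slc30a10 (0.95) and Klk10 (-1.20, adjusted p = 0.0545 for both), Abcg2, Cldn2, Cxcl16, Dnajb9, Plscr1, Smim1, Stc1 and Capn13 did not (adjusted p of at most 0.127), at 87.8% to 104% of their log2 values without it. With the compared groups alone Cybrd1, Cyp4f5 and Capn13 were called and the other 12 were not, such as Tfrc (adjusted p = 0.102), Epas1 (0.0691), Slc30a10 (0.0819) and Klk10 (0.0625). The count of 26 genes was 8 with the pancreas covariate, 0 without the arrays high in pancreas transcripts and 6 with the compared groups alone. Without those arrays Cybrd1 was at 1.64 ± 0.37 (adjusted p = 0.198) and Tfrc at 0.56 ± 0.14 (adjusted p = 0.284) in 4 VSG and 5 sham arrays, and none of the 15 was called (adjusted p from 0.111 to 0.432), at 78.6% to 112% of their log2 values in all arrays.

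**Figure D4:**
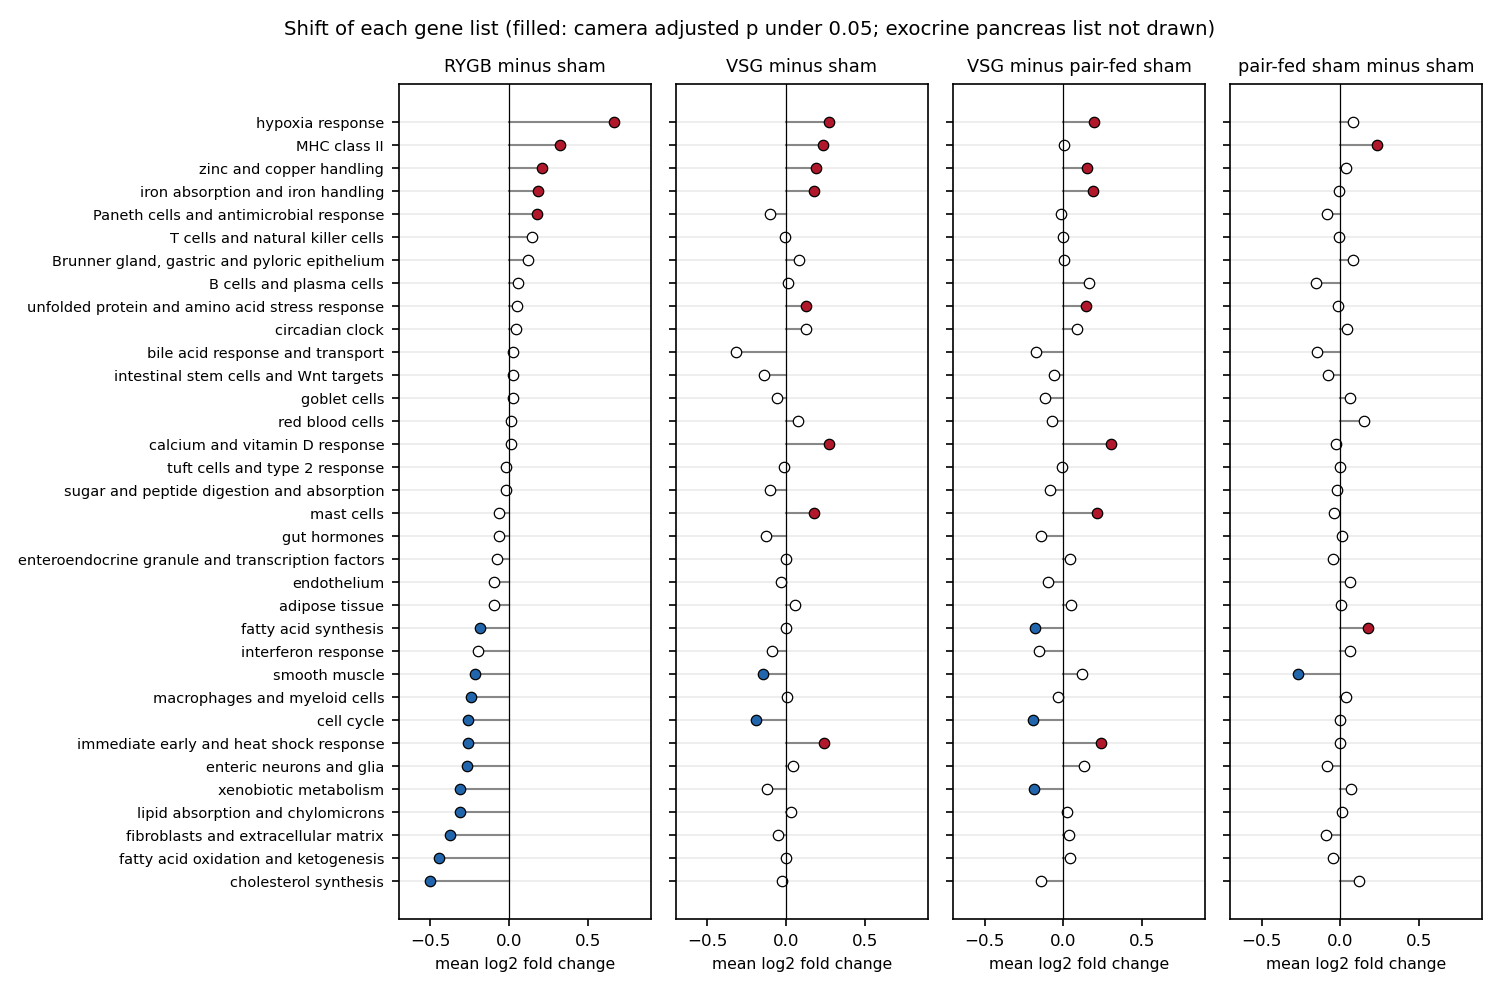
Mean log2 fold change (horizontal axes) of each gene list except exocrine pancreas in the 4 comparisons, with filled points for lists at a camera adjusted p under 0.05. Hypoxia, iron, and zinc and copper lists lie above 0 after both surgeries, and the lipid lists lie below 0 after RYGB, at -0.50 for cholesterol synthesis.

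Pair-fed shams served to separate the effect of VSG from that of eating less. Against them, Cybrd1 was 2.86-fold higher after VSG (1.52 ± 0.28, adjusted p = 0.0099) and Tfrc 1.78-fold higher (0.83 ± 0.11, adjusted p = 0.000531), with all 6 VSG arrays above all 6 pair-fed arrays for both. Slc30a10 rose 2.35-fold (1.23 ± 0.19), Abcb1a, the drug efflux pump, 2.07-fold (1.05 ± 0.24), and the matrix metalloprotease Mmp10 2.05-fold (1.04 ± 0.21). Eif4ebp3 fell 2.38-fold (-1.25 ± 0.24), Klk10 2.24-fold (-1.16 ± 0.23) and Tnfsf10, the death ligand TRAIL, 2.18-fold (-1.13 ± 0.24). Limma called 74 genes, 38 higher and 36 lower. Other named ones were Crybg2 (0.88 ± 0.16), Tnfrsf12a (0.86 ± 0.20) and Plscr1 (0.86 ± 0.17) among the higher, and Cyp4f5 (2.01-fold lower), Gprin3 (-0.99 ± 0.18), Map2k6 (-0.97 ± 0.20), Tmem86b (-0.97 ± 0.22) and Ces2h (-0.93 ± 0.18) among the lower. Of 18 named called genes 9 lost their call with 1 array left out. They were Klk10 without VSG replicate 3 (-1.04, adjusted p = 0.0599), Plscr1 without VSG replicate 6 (0.78, adjusted p = 0.0545), Mmp10 without VSG replicate 2 or 6 or pair-fed replicate 4 (adjusted p of at most 0.0545), and Map2k6 without VSG replicate 1, 2 or 6 or pair-fed replicate 3 (adjusted p of at most 0.0634). The others were Tnfsf10 without VSG replicate 1, 3 or 6 or pair-fed replicate 3, 4 or 6 (adjusted p of at most 0.084), and Abcb1a, Tmem86b, Tnfrsf12a and Ndrg1 without 10, 9, 8 and 8 of the 12 arrays (adjusted p of at most 0.11, 0.0862, 0.109 and 0.0972).

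In this comparison the iron list shifted up by 0.19 (adjusted p = 0.00133, and adjusted p = 0.155 with an estimated correlation), with 2 of 25 members higher, and 6 higher and 1 lower when adjusted over the list alone. Slc40a1 was at 0.48 ± 0.15 (adjusted p = 0.158), Hmox1 at 0.89 ± 0.25 (adjusted p = 0.105) and Heph at 0.16 ± 0.13, none called. The hypoxia list shifted up by 0.19 (adjusted p = 0.00125, and adjusted p = 0.227 with an estimated correlation) with Ndrg1 higher (0.59 ± 0.13), 15 of 16 members not called, and 5 higher when adjusted over the list alone. Calcium and vitamin D response shifted up by 0.30 (adjusted p = 0.000558, and adjusted p = 0.0927 with an estimated correlation) with Cldn2 higher (0.82 ± 0.15), 9 of 10 members not called and 2 higher when adjusted over the list alone. Zinc and copper handling shifted up by 0.15 with Slc30a10 as the called member (adjusted p = 0.0439, and adjusted p = 0.195 with an estimated correlation). Mast cells shifted up by 0.22 (adjusted p = 0.0264, and adjusted p = 0.35 with an estimated correlation), the stress response list by 0.14 (adjusted p = 0.00685, and adjusted p = 0.373 with an estimated correlation) and immediate early genes by 0.24 (adjusted p = 0.0344, and adjusted p = 0.575 with an estimated correlation). No member of these 3 was called, Kit being at 0.43 ± 0.13, Dnajb9 at 0.46 ± 0.12 and Fosb at 1.00 ± 0.24. With the pancreas mean as a covariate zinc and copper handling (0.16, adjusted p = 0.0568) and immediate early genes (0.21, adjusted p = 0.0876) were not called, nor was zinc and copper handling without the arrays high in pancreas transcripts (0.15, adjusted p = 0.115). Zinc and copper handling was not called without VSG replicate 1, 5 or 6 (0.14, 0.16 and 0.15, adjusted p = 0.0542, 0.0607 and 0.0736) or pair-fed replicate 1, 3 or 5 (0.15, 0.14 and 0.13, adjusted p = 0.0598, 0.0756 and 0.12). Mast cells were at 0.15 without VSG replicate 5 (adjusted p = 0.166) and 0.16 without pair-fed replicate 2 (adjusted p = 0.0931), and the stress list at 0.11 without pair-fed replicate 3 (adjusted p = 0.0656). Immediate early genes were not called without VSG replicate 3 or 6 or pair-fed replicate 2 or 3 (0.14, 0.19, 0.22 and 0.21, adjusted p = 0.226, 0.144, 0.0635 and 0.10).

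Lower lists against pair-fed shams were the cell cycle at -0.19 (adjusted p = 9.73e-05, and adjusted p = 0.366 with an estimated correlation), fatty acid synthesis at -0.18 (adjusted p = 0.0299, and adjusted p = 0.483 with an estimated correlation) and xenobiotic metabolism at -0.19 (adjusted p = 0.0164, and adjusted p = 0.444 with an estimated correlation). None of their members fell at the threshold over all genes, Abcb1a rose, and 2, 3 and 4 members fell when adjusted over the list alone. Bub1 was at -0.43 ± 0.12, Scd2 at -0.49 ± 0.18 and Cyp2b1 at -1.46 ± 0.39. In VSG against sham fatty acid synthesis was at -0.0031 (adjusted p = 0.961), and it was higher in pair-fed sham than in sham (0.17, adjusted p = 0.00842, and adjusted p = 0.39 with an estimated correlation). Xenobiotic metabolism was at -0.12 in VSG against sham (adjusted p = 0.447) and 0.07 in pair-fed sham against sham (adjusted p = 0.0842). With the pancreas mean as a covariate fatty acid synthesis was at -0.16 (adjusted p = 0.0717). It was not called without VSG replicate 3 or 6 or pair-fed replicate 3 or 5 (-0.16, -0.14, -0.13 and -0.16, adjusted p = 0.0543, 0.116, 0.127 and 0.054). Xenobiotic metabolism was not called without pair-fed replicate 2 (-0.14, adjusted p = 0.154). The exocrine pancreas list shifted up by 1.47 (adjusted p = 0.00075, and adjusted p = 0.679 with an estimated correlation), and by 0.95, 0.86 and 2.21 without pair-fed replicate 3, 5 or 6. Gcg was at -0.73 ± 0.28, Ghrl at -0.38 ± 0.13 and Gip at -0.0035 ± 0.13, none called. The count of 74 became 48 with the pancreas covariate, 0 without the arrays high in pancreas transcripts and 11 with the compared groups alone. Of 18 named called genes 15 kept their call with the covariate, all but Abcb1a (1.05), Ndrg1 (0.54) and Tnfrsf12a (0.85, adjusted p from 0.0641 to 0.0735 for these 3). Without the arrays high in pancreas transcripts the 18 lay at 74.2% to 103% of their log2 values (adjusted p from 0.0765 to 0.413). With the compared groups alone 6 of the 18 were called, Tfrc, Slc30a10, Cldn2, Crybg2, Cyp4f5 and Ces2h, and Cybrd1 was at an adjusted p of 0.0516.

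Paired feeding alone changed no gene by limma's test, with 0 of 14557 called and 811 at an unadjusted p under 0.05. Tfrc differed by -0.21 ± 0.11 between pair-fed sham and sham, Cybrd1 by 0.11 ± 0.28 and Slc40a1 by 0.08 ± 0.15 (adjusted p = 0.92 for Tfrc and 0.981 for Cybrd1). The smallest p-values belonged to Scd, 2.16-fold higher (1.11 ± 0.25), Hist2h2aa2 (1.06 ± 0.25), Rassf7 (0.52 ± 0.12), Hs1bp3 (0.50 ± 0.11) and Cldn24 (-0.48 ± 0.11), at adjusted p-values of 0.498 or more. Hmox1 was at -0.91 ± 0.25 (adjusted p = 0.537), Heph at 0.03 ± 0.13, Gcg at 0.14 ± 0.28, Ghrl at 0.16 ± 0.13 and Gip at 0.08 ± 0.13. Smooth muscle shifted by -0.27 (adjusted p = 1.74e-06, and adjusted p = 0.227 with an estimated correlation), with 11 of 11 members below 0, Synpo2 at -0.36 ± 0.13, and 2 lower when adjusted over the list alone. MHC class II shifted up by 0.23 (adjusted p = 0.00328, and adjusted p = 0.483 with an estimated correlation), with RT1-DMb at 0.43 ± 0.17, and was at 0.13 without the arrays high in pancreas transcripts (adjusted p = 0.303) and 0.17 without pair-fed replicate 1 (adjusted p = 0.0541). Fatty acid synthesis shifted up by 0.17 (adjusted p = 0.00842, and adjusted p = 0.39 with an estimated correlation), with Scd higher when adjusted over the list alone, and was not called without sham replicate 2 (0.14, adjusted p = 0.0647) or pair-fed replicate 3 (0.13, adjusted p = 0.0541). The iron list was at -0.0072 (adjusted p = 0.952), with a median of 0.027.

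The VSG comparisons share their VSG arrays, so some overlap between them arises without any effect. They shared 13 called genes, 10 higher and 3 lower, including Cybrd1, Tfrc, Slc30a10, Ndrg1, Cldn2, Plscr1, Klk10, Cyp4f5 and Smim1. Neither value of chance measures a shared effect here: the 0 shared calls of simulated unchanged groups follow from groups without an effect, which have few calls to share, and the 0.0574 higher and 0.00989 lower of independent lists leave out the shared arrays. The correlation of fold changes was 0.672 against 0.505 in the simulations, and the covariance 0.0302 against 0.0153. With the VSG arrays split between the comparisons the correlation had a median of 0.28, with 0 to 3 shared calls.

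The effects of RYGB and VSG, each against its own sham, were then compared directly. Only VSG had a pair-fed sham, so these effects include any change in food intake. Across 14557 genes their fold changes correlated with r = 0.34 and rho = 0.184 (permutation p = 0.0099, the smallest that 100 regroupings can give, genes not being independent replicates), where regrouped arrays gave r from -0.254 to 0.286. With all rows of the array tested r was 0.174 (permutation p = 0.0099). The pancreas mean was higher after both surgeries than in their shams, by 3.51 for RYGB and 2.03 for VSG. The correlation was lower with that mean as a covariate and without the arrays high in pancreas transcripts, as given below. A part of r = 0.34 may therefore come from pancreas transcripts. Both surgeries called 15 genes. Of these, 12 were higher after both, such as Cybrd1, Tfrc, Abcg2, Epas1, Ndrg1, Slc30a10, Cxcl16 and Dnajb9, where independent lists would share 0.278. Klk10 and Smim1 were lower after both, where independent lists would share 0.0552, and Abhd5, named after its values were seen, was lower after RYGB and higher after VSG. Of the 385 genes called after RYGB, 276 (71.7%) had the same sign after VSG. The share over all 14557 genes was not taken, so 71.7% cannot be read as a trait of the called genes.

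**Figure D5:**
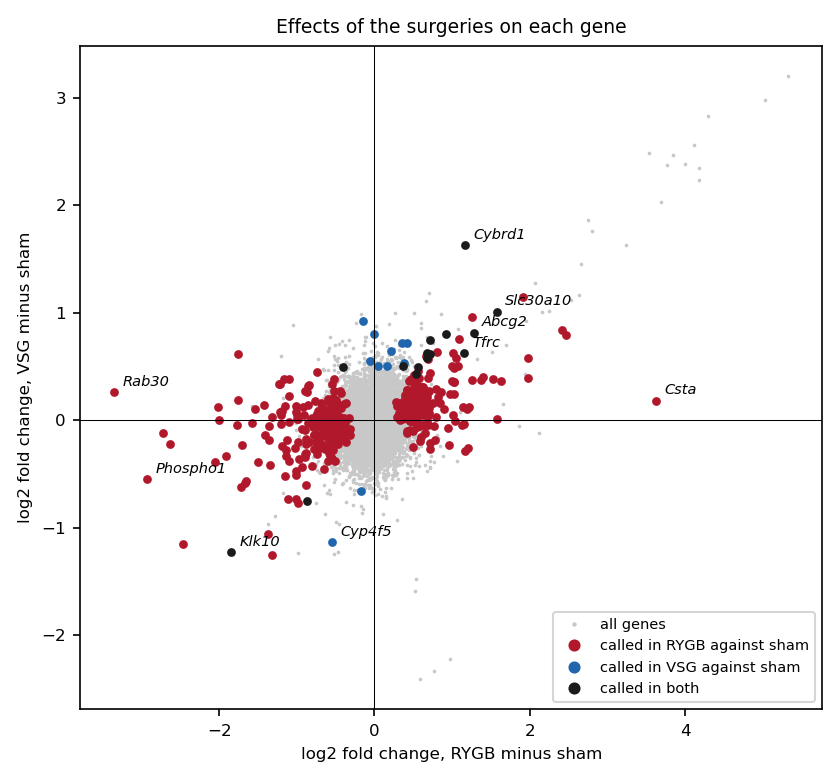
Log2 fold change of each of 14557 genes after VSG (vertical axis) against that after RYGB (horizontal axis), each against its own sham, with called genes coloured. Cybrd1, Slc30a10, Abcg2 and Tfrc are called higher in both, while Rab30, at -3.35 after RYGB, lies near 0 after VSG.

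The test of the difference between the surgeries called 57 genes, 13 with a higher and 44 with a lower effect of RYGB. The largest called differences were in Csta (3.45 ± 0.54), Tbc1d21 (1.58 ± 0.30), Clca5 (1.58 ± 0.34), Lgals5 (1.45 ± 0.34) and Nedd9 (1.39 ± 0.19) on the higher side, and in Rab30 (-3.61 ± 0.51), Ly6m (-2.60 ± 0.53), Angptl4 (-2.41 ± 0.29), Phospho1 (-2.38 ± 0.32) and Gprc5a (-2.38 ± 0.53) on the lower side. The value of Csta may be inexact, since it was at 1.24 to 1.80 in the VSG arrays other than replicate 4 (2.91). Those arrays had medians of 2.84 to 2.92 over all rows. Tfrc differed by 0.52 ± 0.17 (adjusted p = 0.238), Cybrd1 by -0.46 ± 0.40 (adjusted p = 0.839) and Slc40a1 by 0.12 ± 0.21 (adjusted p = 0.95), none called. Lists of lipid metabolism differed, cholesterol synthesis by -0.48 and fatty acid oxidation by -0.44 (adjusted p = 5.15e-08 and 3.33e-11, and adjusted p = 0.198 and 0.056 with an estimated correlation), whereas the iron list differed by 0.0062 (adjusted p = 0.942). Of the 35 lists 13 differed, 3 up and 10 down, and none did with an estimated correlation. The count of 57 genes became 24 without the arrays high in pancreas transcripts, where Clca5, Gprc5a, Lgals5 and Ly6m were not called (adjusted p from 0.256 to 0.46, at 68.0% to 96.7% of their log2 values). Lgals5 was not called with the covariate (adjusted p = 0.066), nor without 15 of the 23 arrays (adjusted p of at most 0.091), Gprc5a without 11 of them (at most 0.0737) and Clca5 without RYGB sham replicate 1 (1.45, adjusted p = 0.0602). The shams of the surgeries gave 0 called genes, with 757 at an unadjusted p under 0.05. The smallest p-values were those of Card9 (0.67 ± 0.16), Ly6g5b (-0.64 ± 0.15), Tmem80 (-0.76 ± 0.20), Mmaa (-0.60 ± 0.16) and Epdr1 (0.70 ± 0.19), all at an adjusted p of 0.88.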

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

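The tests of a response to surgery, of paired feeding and of the share of enterocytes were chosen only after the result was seen, as were the alternatives with the pancreas mean as a covariate or without the arrays high in pancreas transcripts.

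Exocrine pancreas transcripts differed between arrays of a single group. Islet transcripts (Ins1, Ins2 and Ppy) rose and fell with the acinar mean over the 29 group-centred arrays (r = 0.801), and in the 8 arrays with an acinar mean above 8 and the other 21 the ranges overlapped for the 3 genes, as for Ins1 (3.10 to 9.36 and 1.37 to 5.23) and Ppy (3.63 to 5.55 and 3.16 to 4.18). By the correlation, pancreatic tissue carried over with the duodenum is a candidate source of the spread. In the VSG series, a response of the duodenum to surgery as the whole cause is argued against by 3 sham arrays with an acinar mean at or above the median of the surgery arrays, 7.60. They were VSG sham replicate 1 (8.48) and pair-fed replicates 1 and 6 (9.24 and 9.48). The RYGB sham arrays reached at most 5.93, so a response to RYGB is left open by this test. Whether surgery also changed how much pancreas adhered stays open, and no biological explanation of the group difference was tested.

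Of the 25 iron and 16 hypoxia genes measured, 15 were called higher after RYGB and 5 after VSG. Pancreatic tissue as the whole cause is argued against by the covariate: the median of the 15 genes called after RYGB was 0.72 without it and 0.75 with it (104%, 95.9% to 114% with 1 array left out), with a median SE of 0.153 and 0.175, and that of the 5 genes called after VSG was 0.74 and 0.68 (92.2%, 86.3% to 103%), with a median SE of 0.131 and 0.137. With it 11 of the 15 and 4 of the 5 stayed called. In the 21 arrays with a pancreas mean of at most 8, 10 of the 15 and 0 of the 5 were called, at medians of 0.75 and 0.64. This cut did not balance the groups: the VSG arrays kept lay at 4.96 to 7.78, and the VSG sham arrays kept at 2.93 to 6.91. The RYGB arrays kept lay at 3.08 to 7.42, and their shams at 2.88 to 5.93. Values after this cut therefore cannot decide on pancreatic tissue as a cause. Paired feeding gave 21.0% of the VSG median (at most 28.0% with 1 array left out). Both medians subtract the same sham arrays, and the 5 genes were picked as high against them, so this percentage may be inflated. In pair-fed sham against sham Cybrd1 was at 0.11 and Tfrc at -0.21. Against pair-fed sham Cybrd1 (1.52), Tfrc (0.83) and Ndrg1 (0.59) were called after VSG, and Abcg2 (0.53) and Epas1 (0.30) were not. A part of the VSG pattern is thus left open to reduced feeding, which could not be tested for RYGB. An effect of surgery on iron and oxygen-responsive genes may remain as a hypothesis, found and tested on the same arrays.

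In the lists of lipid absorption, cholesterol synthesis, fatty acid synthesis and fatty acid oxidation 18 genes were called lower after RYGB. Their median was -0.75 without and -0.63 with the pancreas covariate (84.5%, 76.2% to 88.8% with 1 array left out), which argues against pancreatic tissue as the whole cause. The calls of 11 of the 18 ended, as the median change shrank and the median SE grew from 0.173 to 0.191 with a covariate that overlaps with the groups, and in the 21 arrays low in pancreas transcripts 5 were called at a median of -0.75. A smaller share of enterocytes was set against the sugar and peptide list, whose median was -1.37% of the lipid median (quartiles of -0.06 and 0.25). That percentage is small in part by selection, since the 18 lipid genes were picked as lower and the sugar genes were not. Taken whole, the lipid absorption list had a median of -0.04 and the sugar list 0.010. In the sugar list 4 members rose and 2 fell when adjusted over the list alone. The sugar list as a whole did not fall, but the comparison does not decide on the share of enterocytes. Food led past the duodenum, which the design gives through RYGB, could account for the fall and was not tested here. Without a pair-fed sham for RYGB, a change in food intake cannot be told apart from it.

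Chance as the source of the groups' differences was tested with 100 splits of the arrays, the real one included. For RYGB against sham 1 split gave as many genes (385, highest other 260), 1 as many lists (17, highest other 16) and 2 as large an iron list shift (0.19, highest other 0.20). For VSG against sham 1 split gave as many genes (26, highest other 5), 1 as many lists (11, highest other 10) and 1 as large an iron shift (0.18, highest other 0.14). For VSG against pair-fed sham 1 split gave as many genes (74, highest other 1), 1 as many lists (11, highest other 10) and 2 as large an iron shift (0.19, highest other 0.19). The difference between the surgeries was reached by 1 split (57 genes, highest other 16). Chance is argued against for the gene counts of these comparisons and of the difference, and for the iron shift of VSG against sham. It is not excluded there, since 100 splits cannot show a share under 1 in 100 and several results were tested. For the list counts, where another split came within 1 list, and for the other 2 iron shifts, which another split exceeded, it is left open although only 1 or 2 of 100 splits reached the real value. It cannot be excluded for the lists of pair-fed sham against sham, where 92 splits gave as many (3, highest other 10), nor for its iron shift, where 85 gave one as large (-0.0072, highest other 0.10). Where limma called 0 genes, in pair-fed sham against sham and between the shams of the surgeries, all 100 splits give as many by construction, so they decide nothing (highest other 2 in both, with 811 and 757 genes at an unadjusted p under 0.05).

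The effects of RYGB and VSG differed by the test of the difference itself (RYGB effect minus VSG effect, log2) in these named genes: Angptl4 (-2.41), Apoc2 (-2.14), Clca5 (1.58), Cpt1a (-0.88), Crybg2 (-1.24), Csta (3.45), Dgat2 (-1.56), Egln3 (1.15), Gprc5a (-2.38), Insig1 (-1.25), Lgals5 (1.45), Ly6m (-2.60), Nedd9 (1.39), Pcna (1.09), Phospho1 (-2.38), Plin2 (-1.64), Rab30 (-3.61), Slc20a1 (-1.35), Slc25a28 (-0.71), Spink4 (-2.01), Tbc1d21 (1.58) and Vip (-1.55). They differed in the means of these lists: hypoxia response (0.39), lipid absorption and chylomicrons (-0.34), cholesterol synthesis (-0.48), fatty acid synthesis (-0.18), fatty acid oxidation and ketogenesis (-0.44), xenobiotic metabolism (-0.19), calcium and vitamin D response (-0.26), Paneth cells and antimicrobial response (0.28), exocrine pancreas (1.48), macrophages and myeloid cells (-0.25), enteric neurons and glia (-0.31), fibroblasts and extracellular matrix (-0.32) and immediate early and heat shock response (-0.50). None of these lists was called with an estimated correlation.

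A single array stood apart from the rest of its group in 43 of 614 group tests of a named gene or list mean, where chance gives about 1 in 20, or 30.7. The tests are not independent, so these counts do not show an excess. Prss1, Ctrb1 and the exocrine pancreas mean, for example, all set RYGB sham replicate 1 apart. The number given is the gap to the nearest other array as a share of the group's range, with the side on which the array lay. Among genes, in RYGB these were Ctrb1 in replicate 5 (below, 0.695), Cybrd1 in replicate 4 (below, 0.668), Fos in replicate 4 (below, 0.65), Prss1 in replicate 5 (below, 0.661) and Slc30a10 in replicate 4 (below, 0.816). In RYGB sham these were Atox1 in replicate 3 (above, 0.716), Col3a1 in replicate 3 (below, 0.766), Ctrb1 in replicate 1 (above, 0.81), Prss1 in replicate 1 (above, 0.856), Reg3g in replicate 2 (above, 0.81) and Tyms in replicate 5 (above, 0.724). In VSG these were Car9 in replicate 6 (below, 0.686), Cenpf in replicate 6 (below, 0.71), Cpa3 in replicate 5 (above, 0.631), Crybg2 in replicate 4 (below, 0.714), Csta in replicate 4 (above, 0.663), Ctrb1 in replicate 4 (below, 0.659), Flna in replicate 5 (above, 0.731), Gata2 in replicate 5 (above, 0.687) and Ghrl in replicate 4 (below, 0.628). In VSG sham these were Capn13 in replicate 6 (below, 0.671), Cdk1 in replicate 4 (below, 0.672), Ier2 in replicate 3 (below, 0.668), Klk10 in replicate 1 (below, 0.707), RT1-Ba in replicate 4 (above, 0.793) and Slc40a1 in replicate 3 (below, 0.632). In pair-fed sham these were Gprin3 in replicate 5 (above, 0.709) and Mmp10 in replicate 4 (below, 0.686). Among list means, in RYGB these were fatty acid synthesis in replicate 1 (below, 0.814), bile acid response and transport in replicate 5 (above, 0.791), xenobiotic metabolism in replicate 6 (below, 0.771), intestinal stem cells and Wnt targets in replicate 1 (below, 0.717), Brunner gland, gastric and pyloric epithelium in replicate 5 (above, 0.672), tuft cells and type 2 response in replicate 5 (above, 0.676) and adipose tissue in replicate 4 (above, 0.626). In RYGB sham these were exocrine pancreas in replicate 1 (above, 0.853), interferon response in replicate 1 (above, 0.723) and enteric neurons and glia in replicate 4 (above, 0.825). In VSG these were mast cells in replicate 5 (above, 0.774) and circadian clock in replicate 2 (below, 0.748). In VSG sham these were intestinal stem cells and Wnt targets in replicate 3 (below, 0.639) and red blood cells in replicate 6 (above, 0.757). In pair-fed sham these were gut hormones in replicate 1 (above, 0.634).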

How the results depend on the processing

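The alternatives with the pancreas covariate and without arrays high in pancreas transcripts were chosen after the data were seen. Under the alternatives fixed beforehand, other than single arrays left out, named genes kept their side of the threshold in 1844 cases, lost a call in 77 and gained one in 25. With 1 array left out these were 2727, 204 and 14, with the covariate 212, 32 and 0, and without the high-pancreas arrays 181, 63 and 0. No value called above changed direction, and the direction of values not called above was not compared. The exocrine pancreas list has no value with the covariate, which is its own mean. The number of arrays limits what small changes can be seen, and the cause of the changes below was not tested, except that leaving out arrays or groups lowers the degrees of freedom and a fold threshold can only lower a count.

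The 385 genes of RYGB against sham became 192 with the compared groups alone, 218 at 1.5-fold or more, 218 with the covariate (199 shared) and 170 without the high-pancreas arrays (149 shared). The 26 of VSG against sham became 6, 17, 8 (8 shared) and 0. The 74 of VSG against pair-fed sham became 11, 48, 48 (46 shared) and 0, and 123 without the lowest 33.3% of genes, 48 with all rows of the array tested and 113 with a trended and robust prior. The 57 of the difference became 24 without the high-pancreas arrays. Pair-fed sham against sham and the comparison of shams stayed at 0 in limma under all of these, with 811 and 757 at an unadjusted p under 0.05.

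With 1 array left out, the counts ran from 284 to 447 for RYGB, from 7 to 24 for VSG against sham, from 17 to 70 for VSG against pair-fed sham and from 45 to 66 for the difference. VSG against sham gave 10 genes without VSG replicate 1, 9 without 2, 7 without 3 and 12 without 6, and 17, 14, 10, 15 and 17 without VSG sham replicates 1 to 5. VSG against pair-fed sham gave 43, 40, 28 and 17 without VSG replicates 1, 2, 3 and 6, and 32, 41, 49 and 37 without pair-fed replicates 3 to 6. Of the named called genes, 40 of 54 in RYGB, 5 of 15 in VSG against sham and 9 of 18 in VSG against pair-fed sham kept their call whichever array was left out. Cybrd1 lost its call in RYGB against sham without RYGB sham replicate 2 (1.10, adjusted p = 0.0689), 4 (1.12, adjusted p = 0.0587) and 5 (0.96, adjusted p = 0.0918). The correlation of the surgeries' effects ran from 0.285 to 0.373 with 1 array left out and from 0.174 (all rows of the array tested) to 0.409 under the alternatives fixed beforehand, and was 0.269 with the covariate and 0.255 without the high-pancreas arrays (permutation p = 0.0099 for both, the smallest that 100 regroupings can give).

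The 17 lists of RYGB against sham became 10 with the covariate, 1 with an estimated correlation and 10 by fry. The 11 of VSG against sham became 5, 0 and 5. Both covariate counts lack exocrine pancreas by construction, since its mean is the covariate. The 11 of VSG against pair-fed sham became 0 with an estimated correlation and 3 by fry. The 3 of pair-fed sham against sham became 5 without the lowest 33.3% of genes, 0 with an estimated correlation and 0 by fry. With 1 array left out they ran from 13 to 17, 9 to 12, 8 to 13 and 2 to 7, the last reaching 5, 7, 5 and 6 without VSG sham replicates 1, 4, 5 and 6, and 7 and 6 without pair-fed replicates 5 and 6.

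The iron list shift of RYGB against sham lost its call with the covariate (0.18, adjusted p = 0.0737), without the high-pancreas arrays (0.18, adjusted p = 0.0786) and with an estimated correlation (0.19, adjusted p = 0.335), with adjusted p from 0.0216 to 0.335 over the alternatives fixed beforehand. With 1 array left out it ran from 0.15 to 0.21, losing its call without RYGB replicate 3 (adjusted p = 0.0672), RYGB replicate 6 (0.0538), RYGB sham replicate 3 (0.0554) and RYGB sham replicate 5 (0.0847). After VSG it lost its call with an estimated correlation alone (0.18 against sham and 0.19 against pair-fed sham, adjusted p = 0.155 for both, from 0.000757 and 0.000877), and with 1 array left out it ran from 0.16 to 0.20 and from 0.16 to 0.21.

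Replicate numbers are not known to pair the arrays. With the replicate number as a block the counts were 242 for RYGB, 5 for VSG against sham, 48 for VSG against pair-fed sham and 33 for the difference, and the RYGB iron shift was 0.17 (adjusted p = 0.0669). The r of arrays with one number, after centring, lay between -0.217 and 0.234, and 1 of 5 RYGB pairs and 2 of 6 VSG and sham pairs matched best with their own number.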

Other observations

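The relations below and the bound against them, r under 0.2, were chosen before their values were seen. That the whole 95% interval must lie under this bound was decided after a first look at the values. Animals with more Tfrc RNA might also have had more Cybrd1 RNA within their group. Over 29 group-centred arrays r was 0.0766 (permutation p = 0.734, adjusted p = 0.734 over 2 relations) and rho 0.058 (permutation p = 0.766), with r = 0.102 without the 2 arrays farthest from the median, r = -0.206 in the 11 arrays of the RYGB series and r = 0.15 in the 18 of the VSG series. The value lies under the bound of 0.2, but by less than its spread: the 95% interval of r, -0.328 to 0.458, includes it and leaves the relation open.

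Animals with more Cybrd1 RNA might also have had a higher mean of the hypoxia list. Over 29 group-centred arrays r was 0.306 (permutation p = 0.0775, adjusted p = 0.155 over 2 relations) and rho 0.462 (permutation p = 0.00886), with r = 0.434 without the 2 arrays farthest from the median, r = 0.346 in the RYGB series and r = 0.295 in the VSG series. The 95% interval of r, -0.10 to 0.63, includes the bound and leaves the relation open.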
